A study of Mus musculus with 6 samples.

How the data were processed

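Paired-end libraries of polyadenylated RNA were made from interscapular brown fat of 6 cold-exposed C57BL/6N mice with a NEBNext Ultra II kit, per the labels' protocols. The series design text names another depot and more replicates than the 6 sample labels, and does not mention the cold exposure that the labels give. The tissue, the treatment and the groups were taken from the sample labels. The groups were 3 control mice (Adcy3 floxed, no Cre) and 3 adipocyte knockout mice (Adcy3 floxed, Adipoq-Cre). The submitters' processing notes name StringTie, Salmon and edgeR and the genome build GRCm38; their versions, settings and annotation release are not given in the sources used here, nor is whether counting used strand.

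The deposited table holds estimated counts per gene that need not be whole (54385 genes in 6 columns), without normalization, per the values in the file. Each column was matched to its sample by the name in the sample's description. Gene symbols and positions came from GENCODE vM21 on GRCm38: 54131 identifiers had a symbol and 254 did not. Of those, 1, ENSMUSG66666620654, differs from all other identifiers in the leading digits of its number. It was kept and tested as a separate entry. Total estimated counts per library were 16563277, 17315577 and 13956786 in controls and 15575196, 15599384 and 17538044 in knockouts. A floor of 3 counts corresponds to between 0.172 and 0.203 CPM in a library. Count ratios carry 95% exact binomial intervals, and intervals and floors cover counting error only.

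Estimated counts were rounded to whole numbers. Genes passing filterByExpr (minimum count 10, minimum total count 15) were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, genotype as the only term), with TMM normalization and Benjamini-Hochberg adjusted p under 0.05. CPM values are counts per 1000000 of TMM-scaled library size. Standard errors are the log2 fold change divided by the root of the F statistic. The common biological coefficient of variation was 25.2%. Gene lists were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 35 lists with at least 5 tested members of 36 lists in all, and again with an estimated correlation. With the preset correlation 18 lists were called, 9 higher and 9 lower; with an estimated correlation none was, the smallest adjusted p being 0.311. Fry, which tests whether a list moves on balance in one direction, called 5 lists (adenylyl cyclases, white adipocyte markers, citrate cycle and pyruvate oxidation, branched-chain amino acid catabolism and lymphocyte markers), and 0 with Adcy3 left out of the cyclase list (adjusted p = 0.0633 for that list). Single values per library were compared with exact permutation tests. Libraries of a group differed by more than sampling noise in a chi-square test, so none was counted as a copy of another. The labels give each as a separate replicate, and the edgeR p-values measure the spread between these samples. Camera compares the genes of a list with all other genes. With the preset correlation its p-values rest on that assumed value, not on how the list's genes varied together between samples. Estimated correlations ranged from -0.12 (lymphocyte markers) to 0.96 (skeletal muscle markers).

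The tests, lists, alternatives and naming rule were fixed before the data were examined. Genes named were every tested adenylyl cyclase; Ucp1, Ppargc1a, Dio2, Elovl3, Cidea, Fgf21, Adrb3, Adipoq, Pparg, Fabp4, Lep and Nr4a1; and up to 10 called genes per direction with the largest changes, a mean of at least 5 CPM and groups that do not overlap, leaving out models named only Gm plus a number or ending in Rik and unnamed identifiers. From each list up to 4 members with the smallest p were added, dropping first the lists with no passing member, to about 40 genes in all. Here a member passed if it did so adjusted over the list alone, and lists were taken in order of their camera p. Genes named outside this rule were chosen after their values were seen, and the text says so.

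Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0 (Wald test), limma-voom, robust dispersion, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out, the 10 most abundant genes and the mitochondrially encoded genes left out of scaling, unrounded values, a test against a fold of 1.5 and an adjusted p under 0.1. Alternatives chosen after seeing the data were muscle marker covariates, knockout library 1 alone against the controls, a correction for transcript length and GC, removal of genes over 2-fold higher in knockout library 1 than in the other 2, the sum of the 2 Adcy3-numbered entries and the cyclase list without Adcy3. With knockout library 1 alone, the controls alone give the spread. Called pseudogene and noncoding entries were aligned to all GENCODE transcripts with blastn 2.17.0. On counts simulated for this comparison, 46% of genes changed 2-fold and 99% of genes changed 4-fold were recovered, with 6 false calls among 151. The changed genes (100 each, among 14415 genes) were drawn from those with a mean of at least 5 CPM. Counts were drawn independently for each gene, without the muscle differences between libraries.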

Results

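Polyadenylated RNA was sequenced from interscapular brown fat, the heat-producing fat depot between the shoulder blades, of 6 mice kept at 5 °C for 24 hours after 20 weeks on a chow diet. In 3 control mice both alleles of Adcy3 were floxed and no Cre was present. In 3 knockout mice the same floxed alleles were combined with Adipoq-Cre, which removes floxed sequence in adipocytes. Adcy3 encodes adenylyl cyclase 3, a membrane enzyme that makes cyclic AMP. The total estimated count per library ranged from 13956786 to 17538044, with 3 libraries in each group. The comparison asks how brown fat of cold-exposed mice differs when its adipocytes lack this enzyme.

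The targeted gene was strongly lower in every knockout library. Adcy3 (ENSMUSG00000020654, GRCm38 chromosome 12, 4133103 to 4213525, plus strand) stood at 154 ± 17.7 counts per 1000000 (CPM) in controls and 25.4 ± 4.36 CPM in knockouts (SD, n = 3 each). The knockout mean was 16.5% of the control mean. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold change was -2.60 with a standard error of 0.17 (adjusted p = 0.00146). The deposited table also holds an entry, ENSMUSG66666620654, that is not a GENCODE gene and whose identifier ends in the same digits as that of Adcy3. The sources used here do not name it. The series title speaks of a truncated form of the enzyme, and whether this entry counts that form is not stated. It stood at 290 ± 45.4 CPM in controls, above Adcy3 itself in each control library, and at 52.5 ± 12.2 CPM in knockouts (SD, n = 3 each). Its log2 fold change was -2.46 with a standard error of 0.20 (edgeR adjusted p = 0.00613). Its share of the 2 entries' summed CPM was 65.2% ± 3.82 in controls and 67.0% ± 5.89 in knockouts (SD, n = 3 each). That difference was within the spread between replicates (exact two-sided permutation p = 0.7, where 3 against 3 cannot go below 0.1). If the 2 entries share exons, their reads were divided by estimation and each level is uncertain; their sum gave a log2 fold change of -2.51. Which exons were floxed is not given in the sources used here. The fall of Adcy3 was no longer past the threshold when the share of muscle marker counts was added as a covariate (log2 fold change -3.14, adjusted p = 0.0819). That of the unnamed entry was past it in 18 of 23 alternatives.

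**Figure D1:**
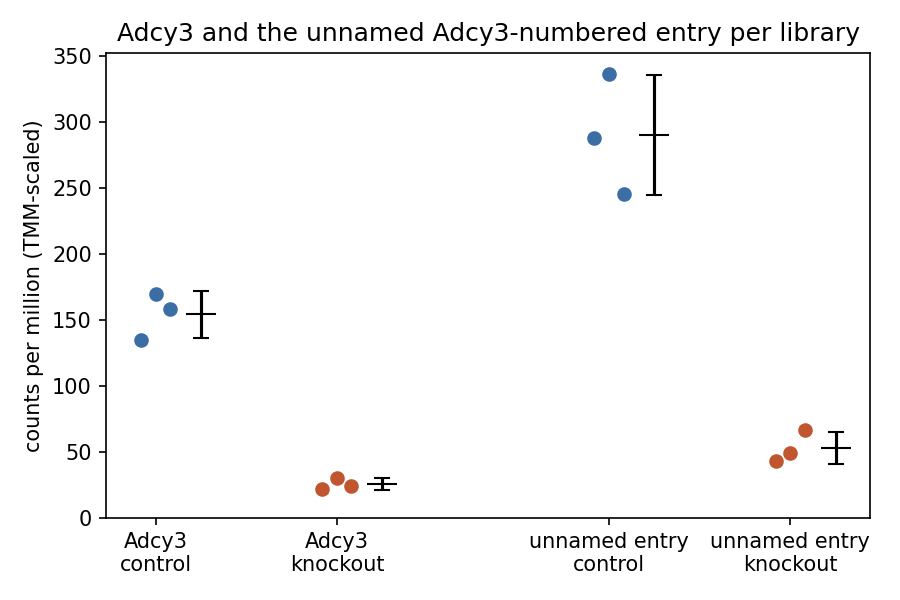
CPM (vertical axis, TMM-scaled) of Adcy3 and of the unnamed entry ENSMUSG66666620654 in the 3 control and 3 knockout libraries. Points are libraries and bars are the mean ± SD. Knockout means were 25.4 and 52.5 CPM, against 154 and 290 CPM in controls.

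Of the other adenylyl cyclases, 7 were tested. Adcy6, the most abundant of them, stood at 187 ± 18.1 CPM in controls and 201 ± 29.2 CPM in knockouts (SD, n = 3 each), with a log2 fold change of 0.10 ± 0.15 (SE). Adcy4 (0.00) and Adcy10 (0.12) were as near to 0. Adcy5 (-1.13), Adcy2 (-2.76) and Adcy7 (-0.62) were lower and passed only when adjusted over the list alone, while Adcy9 (-0.85) did not pass. Over all genes, 1 of the 8 listed cyclases fell, which was Adcy3, and 4 fell adjusted over the list alone. Without Adcy3, which was deleted by design, the list of the other 7 was called lower by camera (median log2 fold change -0.62, adjusted p = 0.0127; adjusted p = 0.416 with an estimated correlation), a test added after seeing the data. With Adcy3 in the list the median was -0.73 (camera adjusted p = 3.04e-07; adjusted p = 0.311 with an estimated correlation). Adcy2 was at 2.78 CPM in knockout library 1 and at 0.0652 and 0.178 CPM in the other 2. Library 1 also had the most muscle marker counts of the 3, as given below. Directions turned without passing when the muscle marker share was a covariate: Adcy2 was then at 1.59, Adcy6 at -0.58, Adcy10 at -1.18 and Adcy4 at -0.12. In the same fit Adcy5 (-2.67), Adcy9 (-3.22) and Adcy7 (-0.57) stayed lower, also without passing.

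Across the transcriptome few genes separated the genotypes past the threshold. Of 14767 genes tested, 4 were higher and 5 were lower in knockouts at an adjusted p under 0.05 (edgeR quasi-likelihood test). Besides the Adcy3 entries, Ppp1r12b, which encodes a regulatory subunit of myosin phosphatase in muscle, fell from 75.3 ± 14.4 to 23.6 ± 4.81 CPM (SD, n = 3 each), with an edgeR log2 fold change of -1.67 ± 0.19 (SE) and an adjusted p of 0.0423. It stood at 29.2, 20.8 and 20.9 CPM in knockout libraries 1 to 3. The gene model 1700025G04Rik fell from 19.7 ± 0.99 to 8.26 ± 0.91 CPM (log2 fold change -1.25 ± 0.14, SE; edgeR adjusted p = 0.0423). Neither stayed past the threshold with the muscle marker score as a covariate, where Ppp1r12b was at -1.36 ± 0.24 (SE, adjusted p = 0.0938) and 1700025G04Rik at -1.06 ± 0.23 (SE, adjusted p = 0.207), smaller falls with larger standard errors. The muscle marker share as a covariate left Ppp1r12b at -0.66 ± 0.30 (SE, adjusted p = 0.357) and 1700025G04Rik at -0.96 ± 0.37 (SE, adjusted p = 0.311). The model was named after its values were seen, as were the Gm models that follow. A processed pseudogene is a copy of a spliced messenger RNA inserted in the genome, and 4 of the 9 called genes carry that annotation.

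These entries were close to absent in one genotype. Morf4l1-ps1 (chromosome 16, 24529394 to 24530362) had 0 counts over the 3 controls and 767 over the 3 knockouts, at least 269-fold higher against a floor of 3 counts over the group, with a 95% exact lower limit of 218 for counting error (edgeR adjusted p = 0.00374). Gm11868 (chromosome 4, 18844202 to 18845679) had 0 and 150 counts, at least 52.6-fold higher against the same floor, with a lower limit of 42.2 (edgeR adjusted p = 0.0278). Gm7049 (chromosome 13, 62813076 to 62814787) had 5 and 1520 counts, a ratio of 320 with a 95% exact interval for counting error of 137 to 986. The long noncoding RNA Gm48795 (chromosome 13, 62813969 to 62815523) lies on the opposite strand across the end of Gm7049, and had 34 and 3230 counts. Reads of this overlapping pair cannot be assigned to one strand where counting is not stated to use strand. In the other direction, Gm8424 (chromosome X, 150924620 to 150926159) had 139 counts in controls and 1 in knockouts, a ratio of 132 with an interval of 23.3 to 5260. Several of these share sequence with an expressed gene, so their counts are uncertain. Morf4l1-ps1 matched Morf4l1 at 99.8% identity over 969 bases, and Morf4l1 itself stood at 141 ± 4.99 CPM in controls and 125 ± 14.4 in knockouts (SD, n = 3 each). Gm7049 and Gm48795 matched Me1 at 98.4% and 98.7% identity, and Gm11868 matched Cyb5r4 at 98.0%. Neither Me1 (log2 fold change 0.08) nor Cyb5r4 (-0.04) passed the test. Me1 changed by 95 ± 160 CPM (SE), against rises of 32.2 CPM for Gm7049 and 68.2 CPM for Gm48795. Cyb5r4 changed by -0.81 ± 2.77 CPM, against 3.19 CPM for Gm11868. A shift of reads of that size could not be seen there. Morf4l1 changed by -16.1 ± 8.78 CPM, against a rise of 16.5 CPM for Morf4l1-ps1. Whether reads moved between them was not tested.

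The number of called genes depended on the libraries and on the test. DESeq2's Wald test called 31 genes higher and 276 lower, and leaving out knockout library 1 gave 45 higher and 812 lower. Gm11868, Gm8424, 1700025G04Rik and Ppp1r12b each lost their call when any library other than knockout library 1 was left out, whereas Adcy3, Gm7049, Gm48795 and Morf4l1-ps1 kept theirs under each such removal.

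Skeletal muscle transcripts differed widely between the libraries. All 20 skeletal muscle markers had a negative log2 fold change (median -2.18), and the list was called lower by camera (adjusted p = 4.98e-14; adjusted p = 0.416 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and the knockout libraries lay far apart. The 20 markers made up 2.24%, 2.00% and 1.70% of counts in control libraries 1 to 3, and 0.962%, 0.0715% and 0.00944% in knockout libraries 1 to 3 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Acta1, skeletal muscle actin, stood at 1793, 91.6 and 5.34 CPM in knockout libraries 1 to 3 and at 2790 ± 252 CPM in controls (SD, n = 3). Ckm, muscle creatine kinase, stood at 866, 38.0 and 2.38 CPM in the knockouts and 1213 ± 166 CPM in controls (SD, n = 3). Both were named after their values were seen. The first principal component held 58.3% of the variance of log2 CPM and placed the libraries in the order of their muscle markers, while the second, with 16.5%, set knockout library 1 apart from the other 5.

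**Figure D2:**
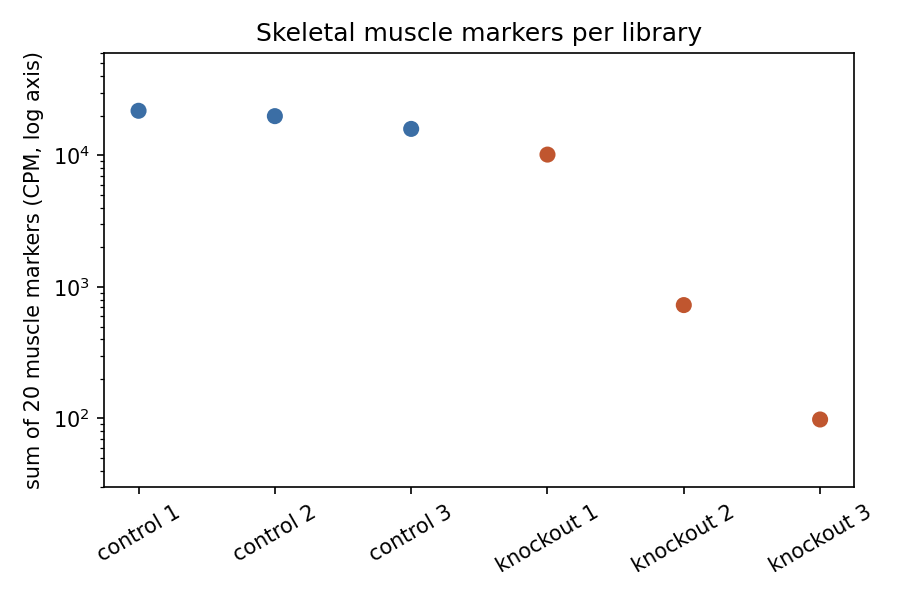
Summed CPM of the 20 skeletal muscle markers (vertical log axis) in each control and knockout library; each point is 1 library. Control libraries lay between 15893 and 21823 CPM, and knockout libraries at 10137, 728 and 98.2 CPM.

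Genes of brown fat identity and heat production were slightly higher in knockouts as a group. Of 29 tested members of the thermogenesis and brown identity list, 27 had a positive log2 fold change (median 0.32), and camera called the list higher (adjusted p = 1.60e-05; adjusted p = 0.416 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Ucp1, the uncoupling protein that makes heat in brown fat mitochondria, stood at 5752 ± 316 CPM in controls and 7288 ± 265 CPM in knockouts (SD, n = 3 each). Every knockout library was above every control, at 1.27 times the control mean, and the edgeR adjusted p was 0.235. Elovl3, a fatty acid elongase induced by cold (0.33 ± 0.12, SE), and Cidea, a lipid droplet protein (0.36 ± 0.14), also had all knockouts above all controls, without passing. Dio2, which activates thyroid hormone (0.28 ± 0.27, SE), Ppargc1a, a coactivator of mitochondrial genes (0.27 ± 0.41), and Adrb3, the beta-3 adrenergic receptor (0.10 ± 0.18), were within about 1 standard error of 0. Fgf21, a hormone secreted by brown fat, was near 1.04 CPM in controls and 2.70 CPM in knockouts, with overlapping groups. The list median lay 0.23, 0.28 and 0.39 above the control mean in knockout libraries 1 to 3. The list was not called with the muscle marker score as a covariate (median 0.29, adjusted p = 0.0636). With the muscle marker share as a covariate the shift was nearly gone (median 0.07, adjusted p = 0.893), and Dio2 (-0.50) and Ppargc1a (-1.08) turned negative without passing.

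Lists of mitochondrial and fuel metabolism were higher as groups, without any member passing over all genes. Of 75 nuclear genes of the respiratory chain, 73 had a positive log2 fold change (median 0.32; camera adjusted p = 1.79e-09; adjusted p = 0.516 with an estimated correlation). Their median lay 0.64 above the control mean in knockout library 1, and 0.04 and 0.23 above it in libraries 2 and 3. The lists of fatty acid oxidation (25 of 30 positive, camera adjusted p = 0.00577) and citrate cycle and pyruvate oxidation (22 of 24, 0.00618) were called higher (adjusted p = 0.476 and adjusted p = 0.416 with an estimated correlation). Lipolysis and lipid handling (23 of 26 positive, camera adjusted p = 0.00730) and glucose uptake and glycolysis (20 of 26, 0.0302) were also called higher (adjusted p = 0.416 and adjusted p = 0.460 with an estimated correlation). Cholesterol synthesis (20 of 22 positive, camera adjusted p = 0.0218) and the mitochondrially encoded genes (12 of 13, 0.0408) were called higher as well (adjusted p = 0.422 and adjusted p = 0.516 with an estimated correlation). The share of counts from mitochondrially encoded genes was 25.1% ± 1.55 in controls and 26.5% ± 1.13 in knockouts (SD, n = 3 each; exact two-sided permutation p = 0.4). Branched-chain amino acid catabolism was called higher (15 of 20 positive, camera adjusted p = 0.0218; adjusted p = 0.416 with an estimated correlation), and 1 member, Bckdhb, rose adjusted over the list alone. Bckdhb encodes a subunit of the dehydrogenase that commits branched-chain keto acids to oxidation. It was chosen after its values were seen and stood at 101 ± 0.86 CPM in controls and 178 ± 18.6 CPM in knockouts (SD, n = 3 each; edgeR adjusted p = 0.0895). With the muscle marker score as a covariate 4 of these 8 lists were no longer called. These were fatty acid oxidation (median 0.20, from 0.24; adjusted p = 0.304), the citrate cycle (0.18, from 0.22; 0.150), the mitochondrially encoded genes (0.19, from 0.22; 0.484) and branched-chain amino acid catabolism (0.02, from 0.16; 0.335). The muscle marker share as a covariate left the estimate to rest mostly on knockout library 1, the library that stood apart on the second principal component. There 7 of the 8 lists were not called (adjusted p from 0.150 to 0.886), yet several medians were larger than without the covariate. Lipolysis was at 0.39 (from 0.20), glycolysis at 0.51 (from 0.23), the mitochondrially encoded genes at 0.33 (from 0.22) and cholesterol synthesis at 0.24 (from 0.15). Fatty acid oxidation was at 0.22 (from 0.24), the citrate cycle at 0.19 (from 0.22) and branched-chain amino acid catabolism at -0.05 (from 0.16). The respiratory chain was still called, at a median of 1.02 (adjusted p = 3.60e-21). It was also highest in knockout library 1, where transcript length and GC explained 29.0% of the variance of deviations. Correcting for that trend, without a muscle covariate, left the respiratory chain median at 0.30 (from 0.32), with 0.10 for all genes. The list was still called there (camera adjusted p = 6.77e-06). The mitochondrially encoded list lost its call in 11 of 22 alternatives and glucose uptake and glycolysis in 9 of 22.

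White adipocyte genes went the other way. Of 14 tested white adipocyte markers, 12 had a negative log2 fold change (median -0.64), and the list was called lower by camera (adjusted p = 3.32e-07; adjusted p = 0.323 with an estimated correlation). Over all genes none fell, and 8 fell adjusted over the list alone. Retn, the adipokine resistin, stood at 39.1 ± 9.20 CPM in controls and 19.0 ± 1.20 CPM in knockouts (SD, n = 3 each). Lep, the satiety hormone leptin, stood at 22.4 ± 3.20 and 12.6 ± 1.04 CPM, Nnat at 15.2 ± 2.11 and 9.75 ± 0.29 CPM, and Slc7a10, a neutral amino acid transporter, at 16.8 ± 4.48 and 10.2 ± 0.22 CPM (SD, n = 3 each). The list median lay 0.66 below the control mean on the log2 scale in each of the 3 knockout libraries, whereas the muscle markers differed among them. The call ended with the muscle marker share as a covariate (median -0.44, adjusted p = 0.121). The broader list of adipocyte identity and adipokines, which shares 3 genes with this list, was not called (median 0.08, camera adjusted p = 0.397). Adipoq (0.08 ± 0.12, SE), Pparg (0.27 ± 0.14) and Fabp4 (0.26 ± 0.13), which mark all adipocytes, did not pass.

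Connective tissue genes were lower together. Of 33 extracellular matrix genes, 29 had a negative log2 fold change (median -0.68; camera adjusted p = 5.64e-13; adjusted p = 0.416 with an estimated correlation). None fell over all genes and 18 fell adjusted over the list alone, among them Col1a1 (-0.98), Fn1 (-0.98), Col5a2 (-0.77) and Col6a3 (-0.76). Col1a1, the main fibrillar collagen chain, stood at 133 ± 22.9 CPM in controls and 67.6 ± 16.7 CPM in knockouts (SD, n = 3 each). The matrix list was not called with the muscle marker share as a covariate (median -0.31, adjusted p = 0.121). The fibroblast and progenitor list was called lower (13 of 16 negative, camera adjusted p = 5.70e-05; adjusted p = 0.422 with an estimated correlation), and 3 members fell adjusted over the list alone: Dpp4 (-1.64), Cd55 (-1.05) and Fbn1 (-0.96). Gsn (-0.68) did not pass. The median of this list lay 0.13 below the control mean in knockout library 1, and 0.77 and 0.93 below it in libraries 2 and 3, the order of the muscle markers. It was not called with the muscle marker score as a covariate (median -0.15, adjusted p = 0.304).

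Immune cell lists were lower as well, with few counts behind them. Macrophage markers (14 of 16 negative, camera adjusted p = 0.00135; adjusted p = 0.498 with an estimated correlation) had 1 member that fell adjusted over the list alone, the scavenger receptor Cd163 (-1.15). Mrc1 (-0.84), Lyve1 (-1.10) and Clec10a (-0.99) did not pass, and were above 0 with the muscle marker share as a covariate (0.14, 0.73 and 0.37). The macrophage median lay 0.01 above the control mean in knockout library 1 and 0.77 and 0.87 below it in libraries 2 and 3. Control libraries 1 to 3 were themselves spread, at 0.18, -0.46 and 0.26 on the same scale. The macrophage call ended with the muscle marker score as a covariate (median 0.07, adjusted p = 0.967). Lymphocyte markers (4 of 6 negative, camera adjusted p = 0.0368) and neutrophil and mast cell markers (6 of 7, 0.0368) were called lower (adjusted p = 0.416 and adjusted p = 0.422 with an estimated correlation). Neither was called with the muscle marker score or share as a covariate. The lymphocyte median shrank from -0.61 to -0.37 with the score (adjusted p = 0.4997) and -0.16 with the share (0.737), whereas the neutrophil and mast cell median of -0.59 was -0.74 (0.374) and -0.59 (0.885). The lymphocyte call was kept in 11 of 21 alternatives and the neutrophil and mast cell call in 9 of 21.

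The creatine and calcium cycling list, which holds routes of heat production that do not use Ucp1, was called lower (11 of 15 negative, median -0.79, camera adjusted p = 0.000807; adjusted p = 0.416 with an estimated correlation). Adjusted over the list alone, 4 members fell and 1 rose. Atp2a2, the calcium pump SERCA2, stood at 680 ± 50.1 CPM in controls and 375 ± 29.5 CPM in knockouts (SD, n = 3 each; edgeR adjusted p = 0.0741), and at 409 CPM in knockout library 1. Slc6a8, the creatine transporter, had a log2 fold change of -0.79 ± 0.17 (SE) and Sln, a regulator of the pump in muscle, of -3.28 ± 1.03. Ckb, the brain-type creatine kinase that acts in brown fat, was the member that rose adjusted over the list alone (0.73 ± 0.23, SE). Muscle expresses several of these genes, Atp2a1 is also in the muscle list, and the list was no longer called with the muscle marker score as a covariate (median -0.02, adjusted p = 0.521).

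**Figure D3:**
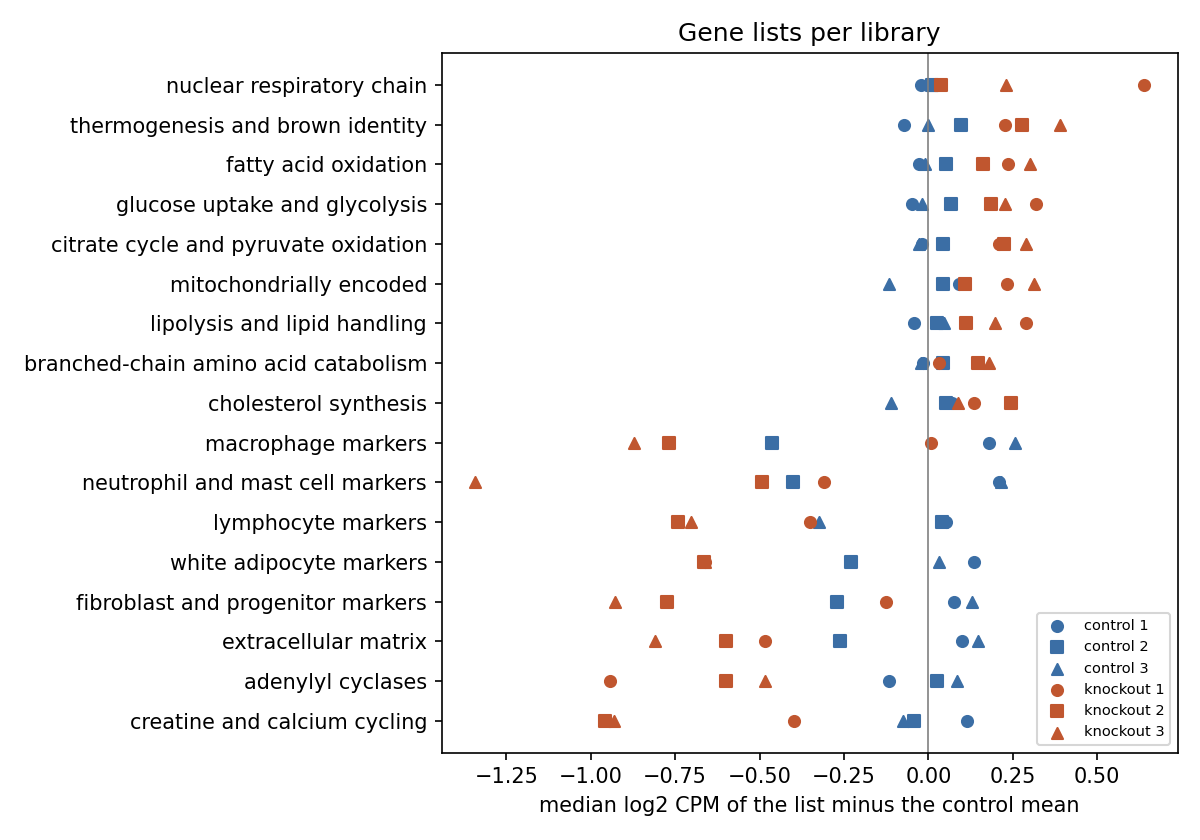
Median over the tested members of each called list, other than the muscle markers, of log2 CPM minus the control mean (horizontal axis), per control and knockout library; each symbol is 1 library. White adipocyte markers lay 0.66 below the control mean in all 3 knockout libraries, whereas the respiratory chain was 0.64 above it in knockout library 1 and 0.04 above it in library 2.

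Early targets of cyclic AMP and its signalling chain were not called as groups. The list of cyclic AMP-induced early genes had 11 positive and 10 negative members (median 0.02, camera adjusted p = 0.559), and Nr4a1, an immediate early gene, had a log2 fold change of -0.50 ± 0.38 (SE). The list of cyclic AMP and protein kinase A signalling was not called (24 of 42 positive, median 0.02, camera direction lower, adjusted p = 0.192). The early genes were called higher with the muscle marker score as a covariate (median 0.23, adjusted p = 0.0445), and the signalling list lower (median -0.14, adjusted p = 0.0401). Leaving out control library 2 also gave a call for the early genes.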

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

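The muscle covariates, knockout library 1 alone, the length and GC correction, the removal of genes high in knockout library 1, the sum of the Adcy3 entries and the cyclase list without Adcy3 were chosen after seeing the data. The Adcy3 log2 fold change ranged from -3.14 to -2.38 over 24 alternatives and kept its call in 23. With the muscle marker share as a covariate it was -3.14 and no longer past the threshold (adjusted p = 0.0819, against 4.04e-46 to 0.0291 in the others), as its standard error rose from 0.17 to 0.38. Leaving out each library gave -2.74 to -2.50.

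Against 4 genes higher and 5 lower, DESeq2 gave 31 and 276, robust dispersion 7 and 39, an adjusted p under 0.1 also 7 and 39, no low-count filter 111 and 782, the muscle marker score as a covariate 10 and 8, knockout library 1 alone 415 and 290, and removal of genes high in that library 11 and 125. The numbers lower were 27 with limma-voom, 3 against a fold of 1.5 and 0 with the muscle marker share as a covariate (3 higher, and 2146 genes at an unadjusted p under 0.05). Leaving out each library gave 3 to 45 higher and 1 to 812 lower; the highest of each came without knockout library 1, while removal of any other library left 1 or 2 lower, with 1 fewer sample. The cause of the other shifts was not tested. RLE factors, the 1 CPM filter and unrounded values kept the same 9 calls.

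Against 18 lists called, camera with an estimated correlation called 0, fry 5, the muscle marker share as a covariate 6 and knockout library 1 alone 8, where the controls alone give the spread; leaving out each library gave 12 to 21. Leaving Adcy3 out of the cyclase list kept 18 with camera and gave 0 with fry. With the muscle marker share as a covariate camera's direction turned, to or from a call, for the skeletal muscle list (median 3.08), creatine and calcium cycling (0.77), macrophage (0.44), fibroblast (0.16), lymphocyte (median -0.16, with camera's direction upward) and circadian clock lists (-0.66), and with the muscle score for the skeletal muscle list (0.00561). Over all alternatives the median changed sign in 43 values of 19 lists, among them Schwann cell markers (0.63) and branched-chain catabolism (-0.05) with the share and macrophage markers (0.07) with the score. These covariates leave the genotype estimate to rest mostly on knockout library 1. Both are built from the skeletal muscle markers, so the turn of the skeletal muscle list is not an independent result.

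The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at 0.07, 0.11 and 0.05 across genes, although each library correlated best with its own number, a hint from the data and not the design. With the replicate block 2 genes were higher and 2 lower, all 4 among the 9.

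Of 1168 values for 51 named genes and entries, 1042 kept their side of the threshold, 41 lost a call, 85 gained 1 and 0 calls reversed. Without a call in either fit, 38 values of 16 genes changed sign, 15 of them with the share, such as Acta1 (3.53), Ckm (3.94), Sln (0.35) and Cd55 (0.10). Acta1 and Ckm are among the markers that make up the share, so their values there are not independent of it. The length and GC correction moved the median log2 fold change of all genes to 0.10. Depth limits the entries near 0 counts, and no list test was made with DESeq2, the fold test or the looser threshold.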

Other observations

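None of the remaining lists fixed before the data were examined was called by camera, although several were under an alternative. In the integrated stress response list (15 of 22 positive, median 0.20, adjusted p = 0.106), members moved apart: Mthfd2, a mitochondrial folate enzyme (log2 fold change 1.23), and Asns, asparagine synthetase (0.55), rose adjusted over the list alone, and Chac1, a glutathione-degrading enzyme (-1.96), fell. Among secreted factors of brown fat (median 0.14, adjusted p = 0.870), Igf1 (-1.22) and Fgf13 (-1.63) fell adjusted over the list alone and Ptgds (0.74) rose. Igf1 stood at 17.4 ± 3.68 CPM in controls and 7.46 ± 0.64 CPM in knockouts (SD, n = 3 each; edgeR adjusted p = 0.0919). These genes were chosen after their values were seen.

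De novo lipogenesis (22 of 26 positive, median 0.15, camera adjusted p = 0.0719) and the interferon response (19 of 24 negative, -0.18, 0.0943) were not called. Nor were Schwann cell and nerve markers (9 of 11 negative, median -0.58, camera adjusted p = 0.0606), the unfolded protein response (17 of 20 positive, 0.10, 0.121), heat shock (12 of 14 positive, 0.19, 0.228) or the circadian clock (12 of 19 positive, 0.14, 0.341). Mural and smooth muscle (median -0.07, camera adjusted p = 0.248), red blood cell (0.26, 0.255), cell cycle (-0.22, 0.270) and endothelial markers (0.06, 0.317) were not called either. Heat shock was called higher with the muscle marker share (median 0.97, adjusted p = 4.12e-05) and score (0.45, 0.000144) as covariates, without control library 2 and without knockout library 3. It was also called with knockout library 1 alone, where the controls alone give the spread. Red blood cell markers were called higher in 3, with the share (median 1.79, adjusted p = 3.78e-06), with the score (0.66, 0.0128) and without control library 1. The integrated stress response and the unfolded protein response were called higher with the score (adjusted p = 0.0401 each), in 3 and 2 alternatives in all. De novo lipogenesis and Schwann cell markers were called in 5 alternatives each and the interferon response in 4. Endothelial markers were called higher without control library 3, mural markers lower without knockout library 1, and the circadian clock lower with the share (median -0.66, adjusted p = 0.0422). The mesothelial and epithelial list had 1 tested member and no test. Genes next to Adcy3 (median 0.04, camera adjusted p = 0.386) held 3 members that fell adjusted over the list alone, Dnmt3a (-0.68), Dnajc27 (-0.64) and Kif3c (-0.81), and 1 that rose, Ptrhd1 (0.55), all named after their values were seen.

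Of the tests below, those of transcript length and GC and of other splits were set before their results were seen. The others were chosen after. The skeletal muscle genes were lower in knockouts by 4.58 in mean log2 CPM, but ranged over 7.39 among the 3 knockout libraries, against an SD of 0.23 in controls. That argues against the genotype alone as the cause, since those libraries share it. Skeletal muscle tissue in some dissections stays open. Of the 20 markers, 19 were ordered knockout 1 above 2 above 3, but the order had been seen beforehand and any change shared by these markers would give it. Tissue in some dissections and a change of muscle genes that differs between mice therefore cannot be told apart here, nor whether the amount of muscle also followed genotype.

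The brown adipocyte list was higher and the white adipocyte list lower in knockouts. Scaling removes a rise shared by most genes (median log2 fold change of all genes 0.01). Dilution by muscle RNA in the controls would therefore raise transcripts that muscle lacks relative to the rest, and not lower them. Yet 8 of 14 white markers fell adjusted over the list alone, which argues against dilution for that list as far as muscle lacks these markers. The rule for this comparison was set after these falls were seen. For the brown list dilution stays open. Its mean shift in knockout 1 was 0.52 ± 0.25 (jackknife SE over genes) of that in knockouts 2 and 3. The brown list median was 0.24 ± 0.13 (SE over genes, not between mice) above that of the adipocyte identity list, which dilution would raise as much. Both values bear on dilution only if muscle lacks the genes of the brown and identity lists, which was not checked. Transcript length and GC explained 29.0% of the variance of deviations in knockout 1 and at most 7.13% in the others, but removing the trend left 0.99 of the difference between the list medians (0.95 against 0.96), which argues against it. White fat left on the control tissue and a change within the knockout adipocytes cannot be told apart. The white list median was -0.64 and that of adipocyte identity 0.08, as either may give. Only 1 Hoxc gene of the list was tested, and it did not fall adjusted over the list alone.

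Some genes beside Adipoq were higher in knockouts. Of the 12 tested genes of that list Kng2, Eif4a2 and Rfc4 rose adjusted over the list alone, while Masp1 (-1.81) and Ahsg (-0.84) fell, and the list was not called (median 0.09, mean -0.04, camera adjusted p = 0.454). The genes named here were chosen after their values were seen. On GRCm38 chromosome 16 the 4 tested genes from Kng2 to Rfc4 (22985854 to 23127737), which end before Adipoq at 23146536, were Kng2 (0.77 ± 0.15, SE), Kng1 (0.40 ± 0.31), Eif4a2 (0.56 ± 0.13) and Rfc4 (0.71 ± 0.20). Their median of 0.64 ± 0.10 (SE over the 4 genes, not between mice) lies near 0.58, the log2 ratio of 3 copies to 2. A candidate explanation is therefore extra copies carried with the Adipoq-Cre transgene, which the controls lacked. That is not shown, since these genes were picked for having risen. Adipoq itself was at 0.08, but which copies the transgene carries was not examined, so that level does not decide either way. A run of 4 adjacent genes as strong occurred in 2.56% of 14390 stretches of 17 tested genes. As the run was picked after its values were seen, this does not exclude a chance run. Muscle dilution would raise adipocyte identity genes as much, and the median of the 4 genes was 0.56 ± 0.16 (SE over genes) above that of the identity list. As the 4 genes were picked for having risen, this difference cannot decide about dilution, which stays open. The ratio of the shift of these 4 genes in knockout 1 to that in knockouts 2 and 3 decided nothing (0.76 ± 0.45, jackknife SE over genes). The loss of Adcy3 stays open and untested, as transgene and knockout were in the same mice.

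The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4 genes higher and 5 lower, against at most 1 in any other split, and was the 1 split of the 10 with a count as large for each. For lists it gave 18, against at most 15, from control libraries 1 and 3 with knockout library 1 against the rest, again 1 split of 10. Of all genes tested, 18.4% separated the groups without overlap, where chance gives 10% on average. Genes do not vary independently: the first principal component, which followed the muscle markers, also set all controls apart from all knockouts. No such share was counted for the other splits, so the excess cannot be assigned to genotype.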
